A study of Mus musculus with 2 samples.

How the data were processed

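Single-cell RNA was measured in 2 libraries from subcutaneous 4T1 tumours, 1 from animals given PBS (control) and 1 from treated animals, with Chromium Single Cell 3′ v3 reagents per the labels' protocols. Deposited values were raw UMI counts per gene and barcode, made with Cell Ranger 8.0.1 per the file headers, and Cell Ranger and STAR are named in the submitters' processing notes. The genome build and gene annotation are not given in the sources used here, and genes are named by the symbols and IDs that the deposited gene table pairs. The authors also deposited a list of the cells they kept, each with its library. No annotation of cell types was used.

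The matrix was assigned to the treated library because all 10835 barcodes listed under the experimental group were in it. Only 37 of 11643 control barcodes were. Counts of the control library were not analysed here, so the comparisons planned between treated and control tumours could not be run. In their place, and chosen after the data were examined, each class was set against all other kept cells of the treated library. The planned selection of genes by their treated to control ratio was therefore void. The remaining part of the rule was used, with the class against the other cells. Up to 4 members of each list reported for a class were selected, those with the largest ratio in either direction and at least 50 UMIs, and a subset of these was printed, picked after their values were seen. Marker genes were named with their level. Cd274, Il1b, Cxcl12 and Ccl5 across classes, the genes of T sub-clusters and of left-out barcodes, and those of the unnamed cluster were also chosen after their values were seen.

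The plan spoke of all barcodes of the matrix as the main set. The 10835 cells kept by the authors were used as the main set, a choice made after the data were examined, and both sets are given. No step the authors used to filter cells is recorded in the sources. The limits of 300 genes, 20000 UMIs and 10% mitochondrial UMIs were read from the values, since no kept cell lies outside them, while 46 barcodes inside all 3 were left out. Of the 1474 barcodes left out, 1097 were at or above the UMI limit, 299 at or above the mitochondrial limit and 98 under the gene limit.

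Cells were clustered with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and leidenalg 0.10.2. Counts were scaled to 10000 per cell and log transformed, 2000 variable genes and 30 principal components were kept, and the Leiden method was run at resolution 1 on a graph of shared neighbours among 15 nearest cells. Mitochondrial, ribosomal protein, haemoglobin, antigen receptor segment and predicted genes were kept out of the variable genes. Clusters were named "X-like" from markers fixed before the data were examined for 18 classes. A cluster took the class with the highest mean log2 level of its markers above the lower quartile over clusters, with at least 3 markers detected. When 2 classes lay within 0.5 of each other, the one with at least 3 more markers among the 10 leading genes was taken, or both names were kept. These scoring rules, and the rule that a cluster led by at least 3 osteoclast genes stays unnamed, were chosen after clusters had been seen. The classes were made from the same counts in which their genes are compared, so genes that define a class are not findings.

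Doublets were scored with the Scrublet method in scanpy 1.11.5. Its own threshold marked no cell, so it had not worked, and removing the 5% of cells with the highest scores was added as an alternative. Free RNA was not subtracted. Mixtures were tested with the fixed markers of each class. For the unnamed cluster its leading genes and macrophage markers were left out of them, and for the T sub-cluster neutrophil and macrophage markers were used where at least 5 times higher in their own class than in the other.

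UMIs were summed over the cells of a class and given in CPM, scaled to a common total, for the 6 classes with at least 100 cells that were planned. Ratios have the exact conditional interval of a ratio of Poisson counts. For each of 31 fixed gene lists, the median log2 ratio (0.5 counts added to each sum) over members with at least 20 UMIs was placed among 10000 random lists of the same size, matched on mean expression in 20 bins, as a description of this library. Of the list genes, 3 were found under another symbol through their gene ID and 2 were not found. Over all lists and classes, 136 of 186 pairs lay outside the middle 95% of random lists, 25 above and 111 below. The text reports 53 pairs that were planned, of which 19 lay above, 19 below and 15 within. Since the comparison profile is mostly myeloid, a list can stand below it because myeloid cells are high. To compare shares of cells with a UMI and cycling shares, each cell was thinned to 1000 UMIs and shallower cells were left out.

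The ratio and list steps were tested on simulated data, in which each class was drawn from the profile of the other cells with 200 genes changed by a factor of 2. Of 100 genes raised, 79 were recovered for tumour epithelial-like, 91 for neutrophil-like, 97 for monocyte/macrophage-like, 65 for T cell-like, 78 for fibroblast-like and 60 for endothelial-like cells, and of 100 lowered, 66, 76, 97, 43, 63 and 43. The intervals held the true ratio for 95.7 to 97.0% of genes. Between 0 and 4 of 31 lists lay outside the middle 95% in these simulations. The simulations drew each UMI independently, so they lacked UMIs gathered in few cells and genes expressed together. They therefore check the calculation and cannot tell whether the intervals are wide enough for real cells.

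The alternatives were all barcodes, another filter on cells, another resolution, the mean over cells in place of the sum, other minimum counts, the median of ratios as scaling, members near their highest class level alone, and no thinning. Those added after the data were examined were the removal of high doublet scores, the other filter for lists, equal weight for every other class, and the other resolutions for cycling shares. The median of ratios shifts list and random medians alike and was applied to single genes. Values under alternatives are given for the 53 planned pairs, a limit set after reversals over all 186 pairs had been counted, and both counts are given.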

Results

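The series comprised 2 single-cell RNA libraries from subcutaneous tumours in mice, 1 per group. The tumours were of 4T1, a mouse breast cancer line that grows in immunocompetent mice. The control animals received PBS, a salt solution, in place of the tested treatment, which the labels call PCN and the series title calls PATCH. Transcripts were counted as unique molecular identifiers (UMIs) on 10x Chromium 3′ v3 libraries. The count matrix analysed here held the treated library, with 12309 barcodes, 33696 genes and 96873409 UMIs. The authors' cell list named 10835 kept cells of the treated library and 11643 of the control library. All 10835 treated barcodes of that list were in the matrix, against 37 of the control barcodes, of which 33 were also treated barcodes. The kept treated cells held 60652188 UMIs, with a median of 3575 UMIs and 1512 genes per cell. Intervals below are 95% intervals, exact Clopper-Pearson for shares and exact Poisson for sums of UMIs. They cover counting error only. The limit that a count of 0 allows is 3 counts over the number of cells, a bound apart from these intervals. With 1 library per group there was no replicate check and no test.

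The design implies a comparison of treated with control tumours. From the data analysed here it could be made only for the number of kept cells, 10835 in the treated and 11643 in the control library, a number that also depends on how many cells were loaded. Counts of the control library were not analysed here, so no value below compares treated with control tumours. What follows describes the treated tumour, each cell class against all other kept cells of that library.

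The treated tumour sample was mostly myeloid. Monocyte/macrophage-like cells made up 46.9% of the kept cells (5080 cells; interval 45.9 to 47.8%) and neutrophil-like cells 37.8% (4092 cells; 36.8 to 38.7%). Tumour epithelial-like cells, named from keratins and epithelial adhesion genes, made up 2.90% (314 cells; 2.59 to 3.23%). Fibroblast-like cells made up 3.0% (325 cells), T cell-like cells 2.53% (274 cells), B cell-like cells 1.09% (118 cells) and endothelial-like cells 0.969% (105 cells). Dendritic cell-like cells made up 0.785% (85 cells), and a cluster with both NK and T cell markers 0.683% (74 cells). The T and NK clusters together held 348 cells, or 3.21% (2.89 to 3.56%). A sub-cluster of 40 of these, 36 of them T cell-like, may be droplets with a T cell and a myeloid cell, as described below. A further 368 cells, 3.40%, formed a cluster led by Ctsk, Acp5, Slc9b2 and Atp6v0d2, genes known from osteoclasts, for which no markers had been fixed, and it stayed unnamed. At resolution 2 of the clustering, 124 of these cells stayed together. Another 243 made up most of a cluster of 274 cells led by cycling genes, which the marker rule named monocyte/macrophage-like. Rgs5, a pericyte gene, was among the leading genes of the endothelial-like cluster, so that cluster also held mural cells.

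The shares depended on the authors' filter. The kept cells all had at least 300 genes, under 20000 UMIs and under 10% mitochondrial UMIs, and these limits left out 1097 barcodes by UMIs. Over all 12309 barcodes, tumour epithelial-like barcodes made up 5.59% (688 barcodes) and fibroblast-like barcodes 4.61% (568 barcodes). With at least 500 genes and under 15% mitochondrial UMIs instead, and no UMI limit, these shares were 6.39% and 4.97%. This setting, called the filter at 500 genes below, clustered its cells anew and held 715 tumour epithelial-like cells, in place of 314. Values under it therefore reflect the lifted UMI limit and the new clusters as well as the gene minimum.

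**Figure D1:**
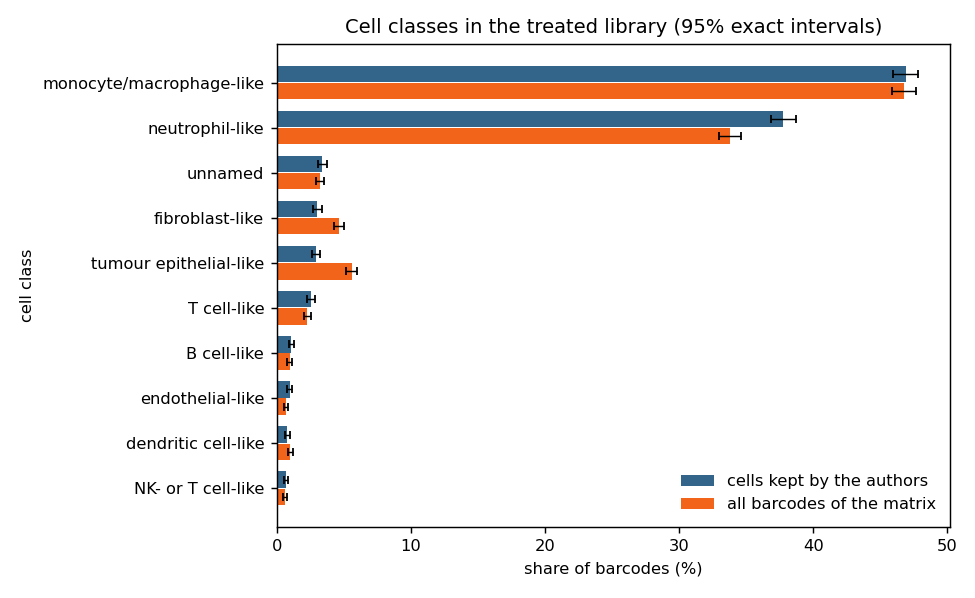
Share of barcodes (%) in each cell class of the treated library, among the 10835 cells kept by the authors and among all 12309 barcodes, each set clustered on its own; error bars are 95% exact intervals. Tumour epithelial-like barcodes made up 2.90% of the first set and 5.59% of the second, and the unnamed class held the cluster led by Ctsk in both sets and, among all barcodes, also a cluster led by mitochondrial genes.

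Tumour epithelial-like cells carried lower levels of most interferon-induced, inflammatory and checkpoint genes than the other, mostly myeloid, cells of the tumour sample. Levels of most cholesterol and fatty acid synthesis genes were higher, but the median of that list was within random lists (percentile 96.9). Of 23 type I interferon response genes measured, 16 had a ratio interval below 1 and 1 above 1. Ifi27l2a was at 12.0 CPM (the UMIs of a gene scaled to a common total per class), 0.0320 times the level in the other cells (interval 0.0230 to 0.0434), and Rsad2, an antiviral enzyme, at 0.166 times (0.114 to 0.235). Of 22 interferon gamma response genes, 13 were below and 3 above, and Cxcl10, a chemokine for activated T cells, was at 0.0569 times (0.0331 to 0.0911). Of 24 NF-kB and inflammatory cytokine genes, 21 were below. Csf2, which encodes GM-CSF, a growth factor for myeloid cells, went the other way, at 28.0 CPM and 34.8 times the other cells (24.3 to 50.7). With the filter at 500 genes, log2 ratios were 2.57 in place of 5.12 for Csf2, −1.06 in place of −4.09 for Cxcl10, −1.27 in place of −2.56 for Rsad2 and −4.19 in place of −4.95 for Ifi27l2a. With the mean over cells they were −2.64 for Cxcl10, −3.45 for Rsad2 and −4.04 for Ifi27l2a. MHC class I presentation genes, which display peptides to CD8 T cells, had 9 of 17 members above and 2 below. Nlrc5, the transactivator of these genes, was at 2.86 times (2.43 to 3.36) and Psmb9 at 0.616 times (0.530 to 0.711).

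Of 21 cholesterol and fatty acid synthesis genes, 17 were above and 1 below in tumour epithelial-like cells, with Sqle, an enzyme of sterol synthesis, at 4.50 times (3.83 to 5.28) and Fasn, the fatty acid synthase, at 2.94 times (2.49 to 3.47). Hypoxia and glycolysis genes were split, with 8 of 23 above and 13 below. Car9, a carbonic anhydrase induced by low oxygen, was at 26.3 times (20.6 to 33.8), and Vegfa at 0.339 times (0.293 to 0.390). Of 22 p53 target and apoptosis genes, 15 were below and 5 above, with Cdkn1a, a cell cycle inhibitor, at 0.0711 times (0.0598 to 0.0839) and Tnfrsf10b, a death receptor, at 6.20 times (4.63 to 8.24). Of 22 oxidative stress genes, 12 were below and 7 above, with Hmox1, which degrades haem, at 0.0979 times (0.0877 to 0.109) and Me1 at 5.35 times (4.17 to 6.80). Twist1, a transcription factor of mesenchymal transition, was at 9.19 times (8.03 to 10.5), and Tgfbi, of the same list, at 0.0517 times (0.0392 to 0.0671). The mesenchymal list had 9 of 21 members above and 12 below. With the filter at 500 genes, log2 ratios were 4.05 in place of 4.72 for Car9, −3.17 in place of −3.81 for Cdkn1a, 1.57 in place of 2.42 for Me1 and 2.07 in place of 3.20 for Twist1. With the mean over cells they were 3.23 for Me1, 4.06 for Twist1, 2.44 in place of 1.56 for Fasn and −3.55 in place of −4.26 for Tgfbi, and without high doublet scores −4.00 in place of −3.35 for Hmox1.

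Against 10000 random lists of matched mean expression, the tumour medians stood at percentile 0 for type I interferon (median log2 ratio −1.25, random median 0.38), 0.120 for interferon gamma (−0.68) and 0 for NF-kB and inflammatory cytokines (−2.74). They stood at percentile 0 for checkpoint and T cell ligands (−2.20, with 11 of 15 members below), 0.130 for p53 targets (−0.92), 0.910 for oxidative stress (−0.55), 0.520 for hypoxia (−0.59) and 2.39 for the mesenchymal list (−0.48). MHC class I stood at 36.3, the unfolded protein and integrated stress response at 9.62 (7 of 22 above, 11 below), oxidative phosphorylation at 3.73 (4 of 23 above, 14 below), immediate early and heat shock genes at 21.8 and cholesterol synthesis at 96.9, all within the middle 95% of random lists. The epithelial list, at percentile 100, partly holds the genes that named the class. Without members below 0.25 times their highest class level, a restriction that by construction takes out members low in the class, the calls of type I interferon (percentile 2.82), interferon gamma (4.66), NF-kB (3.85) and hypoxia genes (5.75) ended, and the checkpoint and mesenchymal medians lay above those of random lists, within their middle 95% (1.02 and 0.54). With every other class at equal weight, the calls of oxidative stress, hypoxia and mesenchymal genes ended (percentiles 13.8, 34.6 and 27.4), the mesenchymal call also ended in 3 other settings, and cholesterol synthesis stood above the middle 95% in 4 settings (percentiles 98.4 to 99.9).

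**Figure D2:**
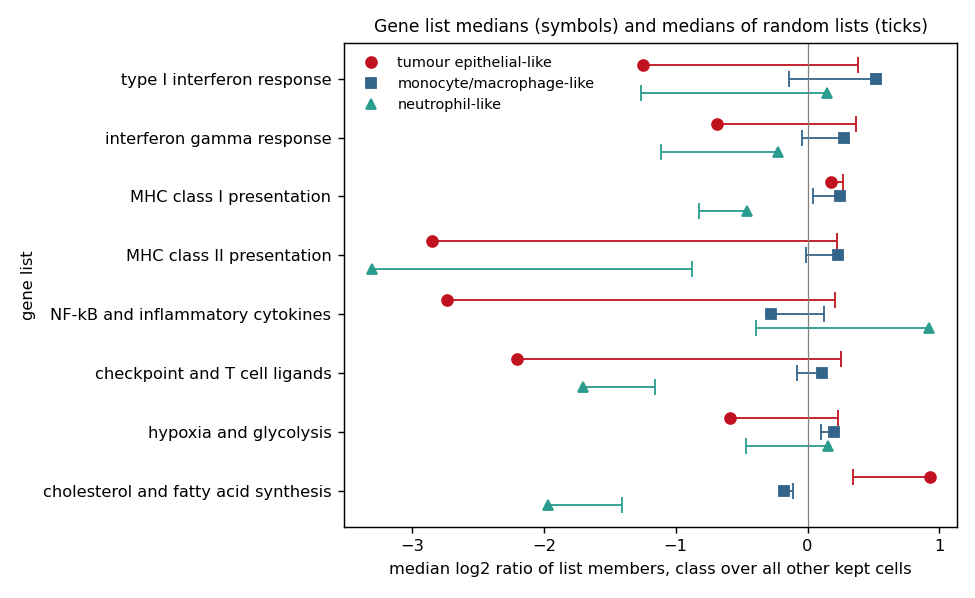
Median log2 ratio of gene list members, class over all other kept cells, for 8 lists in 3 classes of the treated library (symbols), including pairs of list and class that were not planned, joined to the median of 10000 random lists matched on expression (ticks). In tumour epithelial-like cells the type I interferon list lay at −1.25 against 0.38 for random lists, and in monocyte/macrophage-like cells at 0.52 against −0.14.

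Monocyte/macrophage-like cells carried genes of alternatively activated and tumour-associated macrophages and of complement and lipid handling together with interferon-induced genes. Of 20 alternative activation genes, 19 were above and none below. Arg1, which breaks down arginine, was at 1138 CPM and 10.2 times the other cells (9.76 to 10.6), and Ccl24, a chemokine, at 13.5 times (12.9 to 14.2). Of 23 complement, phagocytic receptor and lipid handling genes, 21 were above and 2 below, with Mertk, a receptor for dying cells, at 9.83 times (8.82 to 10.98) and Apoe at 11.7 times (11.5 to 12.0). Of 18 classical activation genes, 13 were above and 5 below, with Fcgr1 at 9.81 times (8.84 to 10.9) and Il12b at 7.43 times (4.23 to 14.3). These 3 lists, which share markers with the class, stood at percentile 100, with median log2 ratios of 2.05, 1.61 and 0.71. Of 23 type I interferon genes, 16 were above and 5 below, with Mx1 at 7.65 times (5.70 to 10.5), and of 22 interferon gamma genes, 13 were above and 6 below, with Irf8 at 4.53 times (4.27 to 4.81). Both interferon lists stood above the middle 95% of random lists (percentiles 100 and 98.6), and with the mean over cells, in which shallow cells weigh as much as deep ones, they stood at percentiles 19.1 and 15.3. The classical activation call ended with that setting too (percentile 85.0). With the filter at 500 genes, log2 ratios were 1.47 in place of 2.84 for Il12b, 2.24 in place of 2.92 for Mx1, 4.08 in place of 3.34 for Arg1, 4.04 in place of 3.29 for Mertk and 4.28 in place of 3.29 for Fcgr1. With the mean over cells they were 3.98 for Arg1 and 4.20 for Mertk, and without high doublet scores 4.36 in place of 3.76 for Ccl24. A cluster of 415 monocyte/macrophage-like cells, 3.83% of the kept cells, was led by interferon-induced genes, Cxcl10, Rsad2, Cxcl11 and Cxcl9 among them.

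MHC class II genes in these cells had 8 of 11 members above and 2 below (percentile 86.8). H2-DMa, a peptide loading factor, was at 4.15 times the other cells (3.84 to 4.49). The median of this list was 0.23, and it was −1.69 (percentile 0.02) when every other class, dendritic cell-like and B cell-like cells among them, was given equal weight, and 0.76 (99.8) with the filter at 500 genes. Hypoxia genes were within random lists (percentile 76.2), at −0.29 with the mean over cells and 0.44 with equal weights, with Vegfa at 2.60 times (2.47 to 2.73). Lymphocyte-attracting chemokines were split, 5 of 12 above and 7 below (median log2 ratio −1.51, percentile 0.03). Cxcl12, which draws lymphocytes and is made by stromal cells, was at 0.0182 times (0.0149 to 0.0220). Without members below 0.25 times their highest class level the median of this list was 1.80 (percentile 99.9). NF-kB and inflammatory cytokine genes had 8 of 24 above and 13 below (percentile 0.6), and the tumour neutrophil list 7 of 23 above and 16 below (percentile 0.385). With every other class at equal weight the medians were 0.21 and 0.69 (percentiles 88.3 and 99.97), and with the filter at 500 genes 0.10 and 0.30 (76.3 and 95.4), so neither call below random lists held. Neutrophil granule genes had 14 of 19 below, with Ngp at 0.00713 times (0.00611 to 0.00826). The median of that list was 0.77 (percentile 97.1) without members below 0.25 times their highest class level. The log2 ratio of Ngp was −5.55 with the filter at 500 genes and −7.76 without high doublet scores, in place of −7.13, and that of Cxcl12 −4.07 with the mean over cells, in place of −5.78.

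Neutrophil-like cells carried inflammatory cytokine and tumour neutrophil genes and little MHC class II. Of 24 NF-kB and inflammatory cytokine genes, 17 were above and 7 below (median log2 ratio 0.92, percentile 99.9). Ccl3, a chemokine for monocytes and other leukocytes, was at 5117 CPM and 10.9 times the other cells (10.7 to 11.04), Cxcl3 at 9.03 times (8.90 to 9.16), and Il6 at 0.0567 times (0.0390 to 0.0798), a log2 ratio of −4.12 that was −3.31 with the filter at 500 genes. Of 23 tumour neutrophil and suppressor genes, 19 were above and 4 below (percentile 100). Acod1, which makes itaconate, was at 42.6 times (41.3 to 43.9) and Siglecf at 18.8 times (11.9 to 30.6), the first of them a marker of the class. All 11 MHC class II genes were below (percentile 0), with H2-DMa at 0.0708 times (0.0544 to 0.0905). Of 20 alternative activation genes 19 were below, and of 23 complement and lipid handling genes 18 were below, both at percentile 0. The calls of NF-kB, alternative activation and complement genes ended without members below 0.25 times their highest class level (percentiles 93.3, 14.4 and 25.4). Hypoxia genes had 13 of 23 above and 9 below (percentile 92.6), with Ero1a at 5.34 times (5.14 to 5.56) and Slc2a1, a glucose transporter, at 4.24 times (4.05 to 4.43). Classical activation genes were within random lists at percentile 29.2. Granule genes, at percentile 100 with 16 of 19 above, largely define the class.

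Interferon genes in neutrophil-like cells were split. A cluster of 167 cells, 1.54% of the kept cells, was led by interferon-induced genes such as Rsad2, Isg15 and Ifit1. Over the whole class, 10 of 23 type I interferon genes were above and 10 below, with Isg15, a ubiquitin-like protein, at 3.83 times (3.62 to 4.06) and Ifi44 at 0.0909 times (0.0662 to 0.122). Of 22 interferon gamma genes, 6 were above and 12 below, with Cxcl9 at 0.0232 times (0.0100 to 0.0459). The medians, 0.15 and −0.23, stood at percentiles 99.96 and 98.5, with random lists at medians of −1.26 and −1.11. Both calls ended without members below 0.25 times their highest class level (percentiles 89.7 and 61.9). Without high doublet scores, log2 ratios were −4.32 in place of −3.44 for Ifi44, which was at −4.03 with the mean over cells, and −6.02 in place of −5.34 for Cxcl9. The median log2 ratio of all genes was −1.37 in neutrophil-like cells. The counts of members above and below and the ratios of single genes are against 1 and do not allow for this shift, while the percentiles do, as random lists share it. Ratios compare shares of UMIs. In these shallow cells, at a median of 1622 UMIs, a ratio above 1 need not mean more UMIs per cell. The median of all genes was 0.27 in tumour epithelial-like, 0.23 in endothelial-like and −0.17 in monocyte/macrophage-like cells. Lymphocyte-attracting chemokines had 9 of 12 members below in neutrophil-like cells (percentile 0) and a median of 1.15 (percentile 76.2) without members below 0.25 times their highest class level.

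T cell-like cells as a class had naive, regulatory and activated transcripts, and Gzma in few cells. Of the 274 cells, 36 were in a sub-cluster that may be droplets with a T cell and a myeloid cell, as described below. Of 14 regulatory T genes measured, 12 were above and 2 below, and of 19 activation and costimulation genes, 11 were above and 5 below. Il2ra, the alpha chain of the interleukin-2 receptor, was at 260 times the other cells (204 to 335) and Icos, a costimulatory receptor, at 310.0 times (244 to 398). Of 16 inhibitory receptor genes, 7 were above and 4 below, with Ctla4 at 176 times (153 to 205) and Pdcd1, which encodes PD-1, at 60.8 CPM and 110.0 times (70.8 to 174). Of 14 naive and memory genes, 13 were above. These 4 lists stood at percentile 100. They hold genes of T cells, some of them markers of the class, and most other cells were myeloid, so this rank is not a finding. By sub-cluster, 74.5% of the Foxp3 UMIs were in the regulatory T-like one. The naive T-like ones of 86 and 50 cells held 59.5% and 27.1% of the Tcf7 UMIs. Foxp3, Il2ra and Ctla4 are fixed markers of regulatory T cells, and Tcf7 of naive T cells. Their place in sub-clusters named from them is therefore not a finding. Of 16 cytotoxic genes measured, 9 were above and 4 below (percentile 99.6), with Gzmb, a granzyme, at 16.3 times (13.8 to 19.2). Of the 186 Gzmb UMIs of the class, 137 (73.7%) came from 23 of the 50 cells of the regulatory T-like sub-cluster, which also held 57.4% of the Il2ra, 60.2% of the Ctla4, 43.1% of the Icos and 28.3% of the Pdcd1 UMIs. A larger part of the Pdcd1 UMIs, 29 of 60 (48.3%), was in the sub-cluster with Il17a among its leading genes, described below. The log2 ratio of Pdcd1 was 7.41 in place of 6.77 with the filter at 500 genes. When every other class was given equal weight, the NK- or T cell-like cluster among them, the median of the cytotoxic list was −1.495 (percentile 0.05) in place of 1.10. It was also within the middle 95% with the mean over cells (95.1) and at a minimum of 100 UMIs (97.2), as was the inhibitory list at that minimum (89.1). Type I interferon genes were below, with 14 of 23 members and none above (percentile 0, and 3.16 with equal weights), and interferon gamma genes stood at percentile 90.2 (99.6 with equal weights), with Socs1, an inhibitor of cytokine signalling, at 7.01 times (5.69 to 8.56).

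After thinning to 1000 UMIs, 9.16% of T cell-like cells had a Cd8a or Cd8b1 UMI (24 of 262; 5.96 to 13.3%), 9.54% a Cd4 UMI (25; 6.27 to 13.8%) and 5.34% a Foxp3 UMI (14; 2.95 to 8.80%). Thinning left out 12 of the 274 cells. Before thinning, at a median of 2950 UMIs, the shares were 19.3%, 24.1% and 13.5%. In B cell-like cells, which should lack these genes, the thinned shares were 0 of 114, which allows a share of up to 2.63%, and at their median of 2364 UMIs 1 of 118 cells had a Cd8a or Cd8b1 UMI. Gzma, a granzyme, was seen in 62.9% of thinned NK- or T cell-like cells (44 of 70) and 0.763% of T cell-like cells (2 of 262), a share under the 1.15% that a count of 0 allows. Sub-clusters of the 348 T and NK cells held 86 and 50 naive T-like, 58 NK-like and 50 regulatory T-like cells. Another 64 cells had Il17a and Il23r among their leading genes, although 8 and 9 of them had a UMI of these. The naming rule left them between CD8 T and gamma delta T or innate lymphoid cells, and none of the fixed CD8 T markers was among their 10 leading genes. A further 40 cells led by S100a9 and S100a8, neutrophil genes, stayed unnamed. Apoe, a fixed monocyte/macrophage marker, was also among their 10 leading genes.

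Most type I interferon genes were low in fibroblast-like cells, and fewer were in endothelial-like cells. Of 23 type I interferon genes, none was above and 16 were below in fibroblast-like cells (percentile 0). In endothelial-like cells none was above, 10 were below and 13 had an interval that includes 1 (percentile 0.01). The endothelial call ended with equal weights (percentile 47.2). Rsad2 in fibroblast-like cells was at 0.0634 times the other cells (0.0337 to 0.109). Of 22 interferon gamma genes, 4 were above and 12 below in fibroblast-like cells and 3 above and 6 below in endothelial-like cells, within random lists at percentiles 5.92 and 5.09, and below them with the mean over cells (0.01 and 0.02). Cxcl9, a chemokine for activated T cells, stood apart in fibroblast-like cells at 183 CPM and 6.70 times the other cells (6.11 to 7.34). Its log2 ratio was 1.97 in place of 2.75 with the filter at 500 genes, and that of Rsad2 was −4.82 in place of −3.92 without high doublet scores. The matrix list in fibroblast-like cells and the endothelial list in endothelial-like cells, at percentile 100, overlap with the markers that named these classes.

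Cycling transcripts were more frequent in tumour epithelial-like than in monocyte/macrophage-like cells and rare in neutrophil-like cells, and their share in the unnamed cluster depended on the clustering. After thinning to 1000 UMIs, 20.4% of tumour epithelial-like cells (58 of 285; 15.8 to 25.5%) had at least 2 G2/M genes, against 5.37% of monocyte/macrophage-like cells (265 of 4935; 4.76 to 6.04%) and 0.767% of neutrophil-like cells (26 of 3389; 0.502 to 1.12%). The tumour share pooled 15.7% in a cluster of 243 cells (38 of 242; 11.4 to 20.9%) and 46.5% in a shallow cluster of 71 cells at a median of 1223 UMIs, of which 43 had enough UMIs for thinning (20 of 43; 31.2 to 62.4%). In NK- or T cell-like cells the share was 12.9% (9 of 70; 6.05 to 23.01%), which overlaps that of tumour epithelial-like cells, and with at least 1 G2/M gene the shares of these classes were 32.9% and 31.2%. The share was 49.7% in the unnamed cluster (180 of 362; 44.5 to 55.0%). Among its cells that stayed in a Ctsk-led cluster, it was 3.75% (3 of 80; 0.780 to 10.6%) with the filter at 500 genes, below the monocyte/macrophage-like share in value but with an interval that holds it, and 26.6% (37 of 139; 19.5 to 34.8%) over all barcodes. It was 21.0% (26 of 124; 14.2 to 29.2%) in the cells that stayed unnamed at resolution 2. It was 64.6% (153 of 237; 58.1 to 70.6%) in those that then made up most of a cluster named monocyte/macrophage-like, with which the share of monocyte/macrophage-like cells was 8.10%. In each of these settings, most cells that left the Ctsk-led cluster joined a cluster with Ube2c and Birc5, cycling genes, among its leading genes. The split was thus partly made on cycling genes, and the shares after it are not findings. The share was 81.7% in a monocyte/macrophage-like cluster that cycling genes such as Birc5 and Top2a lead (215 cells). It was 4.96% in T cell-like cells (13 of 262), 4.73% in fibroblast-like cells (15 of 317) and 7.92% in endothelial-like cells (8 of 101). In dendritic cell-like cells it was 8.24% (7 of 85), and in B cell-like cells 6.14% (7 of 114). Unthinned shares were 57.0% in tumour epithelial-like, 24.4% in monocyte/macrophage-like and 2.49% in neutrophil-like cells, at medians of 11895, 6632 and 1622 UMIs. Thinning left out 703 neutrophil-like, 145 monocyte/macrophage-like and 29 tumour epithelial-like cells. By level, 20 of 29 G2/M genes were above and none below in tumour epithelial-like cells (percentile 88.8), with Cdc20 at 2.88 times (2.44 to 3.38; a log2 ratio of 1.53, and 2.36 with the mean over cells), and 13 of 25 S phase genes were above (percentile 48.8), with Dtl at 5.21 times (4.32 to 6.26). Both lists stood above the middle 95% with the mean over cells (percentiles 100 and 99.4) and with the filter at 500 genes (100 and 99.5). In T cell-like cells, 11 of 25 S phase genes were above (percentile 98.5) and 5 of 29 G2/M genes (percentile 66.8). The S phase call ended in 5 settings (percentiles 75.1 to 97.1), and the G2/M median was −0.80 with the filter at 500 genes.

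**Figure D3:**
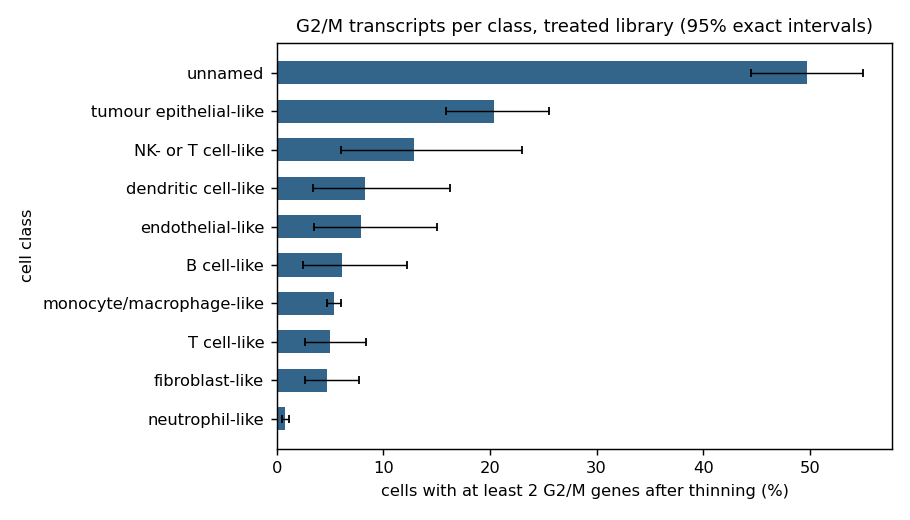
Share of cells (%) with at least 2 G2/M genes after thinning to 1000 UMIs, per cell class of the treated library; error bars are 95% exact intervals. The unnamed cluster stood at 49.7%, tumour epithelial-like cells at 20.4%, NK- or T cell-like cells at 12.9% and neutrophil-like cells at 0.767%. In cells of the unnamed cluster that stayed Ctsk-led at resolution 2, over all barcodes or with the filter at 500 genes, it was 3.75 to 26.6%. Most cells that left joined clusters with cycling genes among their leading genes, so this split was partly made on cycling genes.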

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

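All tests below except that of myeloid markers in tumour-like barcodes and that of doublet scores in the T sub-cluster were chosen after the result was seen. The matrix held 1474 barcodes that the authors' list of kept cells leaves out, a part of the data that the comparisons of kept cells do not use. When all barcodes were clustered, classes with more than the 3 barcodes that a count of 0 allows were present among them. They were 434 tumour epithelial-like, 465 monocyte/macrophage-like, 243 fibroblast-like, 55 neutrophil-like, 37 dendritic cell-like, 17 endothelial-like and 18 mast cell- or basophil-like barcodes. A further 7 had fibroblast and mural markers, 4 were NK- or T cell-like, and 191 were in unnamed clusters.

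Of the 688 tumour epithelial-like barcodes, 63.1% (59.3 to 66.7%) were left out, against 1.32% of neutrophil-like ones, and 399 of them had at least 20000 UMIs. Droplets with a tumour and a myeloid cell would carry myeloid markers, but the share of UMIs from 26 neutrophil and macrophage markers was 0.140% in these 399 barcodes and 0.172% in kept tumour epithelial-like cells, an excess of −0.838% of the difference between myeloid and kept tumour epithelial-like cells, and 17 of the 399 reached 15% of that difference. The test was first run with macrophages alone as the reference (an excess of −1.475% and 31 barcodes) and rerun with all myeloid cells as its prediction had named. Macrophages carried a lower share of these markers (2.31%) than all myeloid cells (3.94%), so a droplet with 1 median macrophage could stay under the 15%. The count of 17 can therefore miss such droplets. The 399 barcodes were also picked as tumour-like by clustering, which can set aside barcodes with much myeloid RNA. Random pairing of tumour cells would give 38.5 such barcodes if every droplet held 2 cells, against 399 seen (361 to 440). This takes the tumour share of barcodes as that of cells. The share of cells would be higher if mixed droplets were set aside by clustering, so 38.5 is not an upper limit. Random pairing at a higher tumour share was not tested. Tumour cells that stuck together before loading, and tumour cells with more RNA, remain open, and no biological explanation was tested, since the design gives no group within this library.

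The unnamed cluster of 368 cells led by osteoclast genes could be droplets that held a macrophage and a cell of another class. The second cell would bring its own markers. Markers of the 8 other named classes, without the cluster's leading genes, were therefore compared with their level in macrophages. Their excess was −5.39 to 0.0249% of the difference between those classes and macrophages. Of the cluster's cells, 6.25% (4.00 to 9.23%) were among the top 5% of doublet scores, from a caller whose own threshold marked no cell. As a measure of free RNA, the share of UMIs from neutrophil markers was 0.651 times (0.629 to 0.673) its median in the classes other than neutrophils. The same amount of free RNA makes a smaller share in deep cells. The cluster had a median of 11077 UMIs, against 6632 UMIs in monocyte/macrophage-like cells. The ratio therefore cannot tell whether droplets of the cluster held more free RNA than other cells. Of 4 osteoclast genes not among its leading genes, Calcr, Nfatc1 and Ocstamp were above the highest named class, and Dcstamp, at 79.1 CPM, was below the 139 CPM of dendritic cell-like cells. At resolution 2 only 124 of the cells stayed in a cluster led by Ctsk, in which the highest excess was 0.0632% and the neutrophil markers were at 0.691 times, and no biological explanation was tested.

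The T sub-cluster of 40 barcodes led by S100a9 and S100a8 may be droplets with a T cell and a myeloid cell. Of its barcodes, 87.5% (73.2 to 95.8%) were among the top 5% of doublet scores, against 2.92% of the other 308 T and NK barcodes. The sub-cluster was noticed for its myeloid genes, which themselves raise a doublet score, and the caller's own threshold marked no cell. The scores therefore cannot tell such droplets from T cells that carry myeloid RNA for another reason. The median of the sub-cluster was 5067 UMIs against 2819 UMIs, and 29 of its barcodes had a Cd3 UMI. S100a9 was seen in 24 of the 40, with at least 5 UMIs in 15, against 104 and 9 of the other 308 barcodes. Free RNA from 1 source would keep neutrophil and macrophage markers in 1 ratio, but of 34 barcodes with at least 10 UMIs of these, 28 had at least 90% of them from 1 class (15 macrophage, 13 neutrophil), against 0.187 at the pooled ratio. No biological explanation was tested.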

How the results depend on the processing

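The removal of the top 5% of doublet scores, the filter at 500 genes for lists, the equal weight of classes and the resolution for cycling shares were chosen after the data were seen, and the other settings before. No paired analysis was possible because each group had 1 library. The doublet caller's own threshold marked no cell and gave no value, and the median of ratios moves list and random medians alike. Of 136 pairs of list and class outside random lists, the same call was kept by 136 at a minimum of 5 UMIs, 133 at 100 UMIs, 123 with the mean over cells, 130 without high doublet scores, 123 with the filter at 500 genes and 119 with equal weights. Without members below 0.25 times their highest class level, 56 of 140 pairs lay outside and 37 calls were kept, as that restriction takes out members low in the class. Over all 186 pairs and all settings, 39 values changed side of the random median after a call and 67 calls ended. Over the 53 planned pairs, 13 changed side, 29 calls ended, 21 arose and 305 were the same. Of 203 named pairs of gene and class, the log2 ratio left its interval in 105 with the mean over cells, 95 with the filter at 500 genes, 84 with the median of ratios and 59 without high doublet scores. Counted over all 203, inside their interval or not, 71, 70, 39 and 29 moved by over 1.5 times. A reversal was counted in 1 further pair with each of the first 2 settings. With the filter at 500 genes the sign also changed for Kif20b in T cell-like cells (0.95 to −0.33), which is counted among the 95. Where no cause is named below, the cause was not tested.

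Over all barcodes, shares were 5.59% tumour epithelial-like, 33.8% neutrophil-like, 4.61% fibroblast-like, 0.707% endothelial-like and 1.02% dendritic cell-like. Of the barcodes that enter, 399 of 434 tumour epithelial-like and 238 of 243 fibroblast-like ones were at or above the UMI limit, and 42 barcodes formed a separate cluster with fibroblast and mural markers. With at least 500 genes, under 15% mitochondrial UMIs and no UMI limit they were 6.39% tumour epithelial-like, 29.6% neutrophil-like, 51.2% monocyte/macrophage-like, 4.97% fibroblast-like, 1.10% dendritic cell-like and 1.32% unnamed. Outside tumour-like cells, neutrophil-like cells made up 38.9% and monocyte/macrophage-like cells 48.3%. At resolution 0.5 the shares were 48.4% monocyte/macrophage-like, 3.21% T cell-like, 0.637% endothelial-like and 0 for NK- or T cell-like and for dendritic cell-like cells. At resolution 2 they were 49.9% monocyte/macrophage-like, 1.14% unnamed and 0 for dendritic cell-like cells. Merged clusters show the cause of the shares of 0.

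With the mean over cells, medians were 0.68 for mesenchymal genes in tumour epithelial-like cells, and 0.11 for interferon gamma and 0.039 for type I interferon genes in monocyte/macrophage-like cells, where Cxcl5 was at a log2 ratio of 0.20. Without members below 0.25 times their highest class level, they were 1.02 for checkpoint and 0.54 for mesenchymal genes in tumour epithelial-like cells, 1.15 for chemokines in neutrophil-like cells, and 0.77 for granule genes and 1.80 for chemokines in monocyte/macrophage-like cells. With the filter at 500 genes, they were 0.10 for NF-kB and 0.30 for tumour neutrophil genes in monocyte/macrophage-like cells, and Kif23 in T cell-like cells was at −0.045. With equal weights, they were 0.21 and 0.69 for the same lists, and −1.495 for cytotoxic genes in T cell-like cells, as NK- or T cell-like cells then weigh more.

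With at least 1 G2/M gene, cycling shares were 31.2% in tumour epithelial-like, 9.74% in neutrophil-like, 16.6% in monocyte/macrophage-like, 19.8% in T cell-like and 11.7% in fibroblast-like cells, and 32.9% in NK- or T cell-like (23 of 70) and 68.2% in unnamed cells. With at least 3 they were 14.7%, 0.177% and 3.20% in the first 3 of these, 1.98% in endothelial-like and 38.9% in unnamed cells. Unthinned, with more UMIs per cell, they were 57.0%, 2.49%, 24.4%, 14.2% and 24.0% in the same order, 19.0% in endothelial-like, 24.3% in NK- or T cell-like and 82.3% in unnamed cells. In B cell-like and dendritic cell-like cells the shares were 19.3% and 22.35% with at least 1 gene, and 11.9% and 31.8% unthinned. With the classes of resolution 2 they were 21.0% in unnamed and 8.10% in monocyte/macrophage-like cells, since 243 cells changed class. Of the unnamed cells, those that stayed in a Ctsk-led cluster had 3.75% (3 of 80) with the filter at 500 genes and 26.6% (37 of 139) over all barcodes. Most of the others joined clusters with cycling genes among their leading genes. With resolution 0.5, the tumour, neutrophil, macrophage, T, fibroblast, endothelial and unnamed shares stayed within their intervals, and no others were run. Unthinned shares of T cell-like cells with a UMI were 19.3% for Cd8a or Cd8b1, 24.1% for Cd4 and 13.5% for Foxp3.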

Other observations

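The tests and comparisons here were all chosen after the data were seen. Cd274, which encodes the checkpoint ligand PD-L1, was at 597 CPM in neutrophil-like cells (581 to 614) and 413 CPM in dendritic cell-like cells (366 to 464), and at 27.7 CPM in tumour epithelial-like cells (22.4 to 33.9). Il1b, an inflammatory cytokine, was at 9559 CPM in neutrophil-like and 2263 CPM in monocyte/macrophage-like cells. Cxcl12 was at 912 CPM in fibroblast-like and 194 CPM in endothelial-like cells, and under 4 CPM in tumour epithelial-like, neutrophil-like and monocyte/macrophage-like cells. Ccl5, a chemokine for T cells, was at 3144 CPM in the NK- or T cell-like cluster and 51.7 CPM in T cell-like cells. Free RNA was not subtracted from these levels. They are shares of the UMIs of a class, and depth differed between classes. The median was 1622 UMIs in neutrophil-like, 6632 in monocyte/macrophage-like and 7575 in dendritic cell-like cells. A higher CPM in neutrophil-like cells therefore need not mean more UMIs per cell.

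Among the T and NK sub-clusters, the NK-like cells held Gzma at 3747 CPM (3526 to 3978) and Prf1, the pore-forming protein of killer cells, at 500 CPM (421 to 589). The regulatory T-like cells held Ctla4 at 2646 CPM (2404 to 2904) and Tnfrsf9 at 2268 CPM (2045 to 2508), against 333 and 253 CPM in the other sub-clusters. In the 64 cells with Il17a among their leading genes, its 275 UMIs came from 8 cells, and no level over the sub-cluster is given. These genes are partly those that set the sub-clusters apart.

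Among tumour epithelial-like barcodes of the clustering of all barcodes, those at or above 20000 UMIs carried G2/M transcripts more often than those below. After thinning to 1000 UMIs, 36.8% of them (147 of 399; 32.1 to 41.8%) had at least 2 G2/M genes, against 17.6% (50 of 284; 13.4 to 22.5%). Thinning left out 0 and 5 barcodes. The lower group held 11 of the 71 cells of the shallow tumour epithelial-like cluster of kept cells, as 59 of them fell in an unnamed cluster led by mitochondrial genes. The share in that shallow cluster, 46.5% (20 of 43; 31.2 to 62.4%), overlapped that of the barcodes with many UMIs, so the share did not rise steadily with UMIs. In all kept tumour epithelial-like cells it was 20.4%.

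The 18 mast cell- or basophil-like barcodes lay inside all 3 limits of the authors' filter, and all 18 had Cpa3, Cma1, Mcpt4 and Fcer1a UMIs, genes of mast cells. None was among the kept cells. Of the 37 left-out dendritic cell-like barcodes, 27 also lay inside the limits, and of these 17 had a Ccr7 UMI, 16 an Fscn1 UMI and 10 a Siglech UMI, genes of migratory and plasmacytoid dendritic cells. In the kept dendritic cell-like cells of the same clustering, the numbers were 17, 2 and 2 of 88. Why they were left out is not recorded in the sources used here.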
